A study of Mus musculus with 12 samples.

How the data were processed

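RNA was measured in 12 libraries of NK cells from spleens of C57BL/6 mice, 3 in each of 4 groups: wild-type and Mirc11-/-, unchallenged and challenged with Listeria. Per the labels, the cells were isolated by negative selection, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. Per the submitters' processing notes, bcl2fastq, Trim Galore 0.4.1, Bowtie2 2.2.8, RSEM 1.3.0 and the GRCm38 genome were used. RSEM yields estimated counts, whereas the values analysed here were whole numbers, and how they were rounded is not given in the sources used here. The annotation release behind them is also not given in the sources used here. The unit of the values deposited by the authors is the count, per gene and library, without normalization. The table held 50643 genes with 12 value columns, all of which were used.

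Library totals ran from 17624530 to 23665679 counts. A single count was worth 0.042 to 0.0561 CPM, and 3 counts over a group of 3 libraries, the floor used for genes at 0, were worth 0.051 CPM in unchallenged wild-type and 0.0496 CPM in unchallenged knockout. Reads carry no molecular identifiers, so floors cover counting error only. Libraries were compared pairwise for duplicated columns, with a ratio of squared differences to counting noise (1 if only counting noise separates them) of 3.38 to 26.9 within groups, and no duplicate was seen.

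Groups, lists, tests and alternatives were chosen before the data were examined, except where stated. Low counts were filtered with filterByExpr over the 4 groups, which kept 16694 genes, and library sizes were scaled by TMM. All 12 libraries were fitted in 1 model with a term per group using the robust quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all tested genes within each of 6 contrasts, and a gene was called at an adjusted p below 0.05 without a fold threshold. The contrasts were challenge in each genotype, knockout minus wild-type in each treatment, the average of these, and the difference between the challenge responses. Every adjusted p given for a gene comes from that test. Standard errors were derived from each gene's log2 fold change and its F statistic. Group levels are mean CPM with SD.

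Named genes followed a rule. For each contrast it took the 8 largest changes per direction among called genes with at least 5 CPM in the higher group and, for pairwise contrasts, no overlap between libraries, leaving out immunoglobulin and T cell receptor segments and clone-named genes. It added up to 4 members of each list with the smallest p, and a fixed set of effector, receptor and signalling genes. Gm26532, Gm37352 and other genes described as chosen after the values were seen fall outside it. Groups that do not overlap arise by chance in 10% of genes at 3 against 3 libraries.

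The 35 fixed gene lists covered the Mirc11 locus (6 members, 0 of them tested), ubiquitin modifiers, TRAF6 to NF-kB signalling, AP-1 factors, MAP kinases, immediate early genes, cytokines, cytotoxic granules, NK receptors, NK transcription factors, interferon targets, cell cycle, metabolism, protein synthesis and folding, apoptosis, p53 targets, sex-linked and mitochondrial transcripts and markers of other cell types. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log CPM with a prior count of 2, adjusted over the lists within a contrast. Where a call was lost with an estimated correlation, that adjusted p is given; cytokines and heat shock genes kept their calls in both challenge contrasts, in the challenged genotype contrast and in the interaction, heat shock genes in the averaged one, and B cell, T cell, neutrophil, erythroid, platelet and mast cell markers in the unchallenged one. A list's camera test asks whether it moves more than other genes. Medians of lists with members at 0 in a group were recomputed with those members at their lower bounds.

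Sites of the 3 microRNAs (7mer-m8 and 8mer) were searched in the longest 3' UTR of each gene, derived from the GENCODE vM21 annotation and transcript sequences. Median shifts were compared with 10000 random lists matched on UTR length (10 strata) and expression (5 strata), where 0.0002 is the smallest p possible, and with 100 shuffled seeds. The random lists were drawn with replacement from genes without a site, so their p-values are resampling p-values over genes, not over libraries. Genes within 10 Mb of the locus were compared with the rest by Fisher's exact test. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

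Replicate numbers were not used to pair libraries. Between the genotypes, residuals of libraries with the same number correlated at 0.12, -0.048 and 0.006 without challenge and at -0.317, 0.058 and -0.148 after it. Across challenge they correlated at 0.016 and 0.144 in wild-type and at 0.249 and 0.024 in knockout. Different numbers there gave -0.179 to 0.158 and -0.264 to 0.277. The values thus gave no sign that the numbers mark pairs, although residuals around means of 3 libraries cannot exclude it. Alternatives were RLE and upper-quartile scaling, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, a non-robust fit, replicate blocks, fits on the compared libraries only, removal of immunoglobulin, T cell receptor, haemoglobin and mitochondrial genes, a 2-fold threshold, camera with an estimated correlation, fry, each library left out in turn and, chosen after the values were seen, removal of genes on X and Y and of markers of other cells.

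The fit was also tested on simulated data with 200 genes changed, spread over changes of 1.5-, 2- and 4-fold. In the unchallenged genotype contrast it recovered 58.2% of changes of 1.5-fold, 61.2% of 2-fold and 89.4% of 4-fold, and in the interaction 23.9%, 59.7% and 84.8%. Of the calls, 4.14% and 5.88% were on unchanged genes. Small changes may therefore go undetected. The 200 changed genes are fewer than the 1955 and 5876 called in these contrasts of the real data, so recovery may differ there. A simulated raised list was called (camera adjusted p = 1.23e-84) and 0 of 30 unchanged lists were. Genes were simulated independently, so this does not test lists whose members move together, such as ribosomal protein genes (estimated correlation 0.609). No file was left out.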

Results

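Natural killer (NK) cells, innate lymphocytes that kill infected cells and secrete cytokines, were isolated from mouse spleen by negative selection, which removes other cells rather than capturing NK cells. The 12 libraries form 4 groups of 3: wild-type and Mirc11-/- (here knockout), each with and without a challenge with Listeria, an intracellular bacterium. Mirc11 is the microRNA cluster that encodes miR-23a, miR-27a and miR-24-2, and the series title places its action on ubiquitin modifiers and on signalling through TRAF6 to NF-kB and AP-1. The terms wild-type and knockout refer to the labels throughout. The dose, route and duration of the challenge are not given in the sources used here. Libraries held 17624530 to 23665679 assigned counts, and 16694 of 50643 listed genes had enough counts to be tested. The labels call the libraries biological replicates without saying that each came from a separate animal, so the p-values may not measure the spread between animals. Sex-linked transcripts, given below, differed between libraries of unchallenged wild-type and of challenged knockout, so those libraries did not all hold the same RNA. Levels are counts scaled by library size (CPM), given as mean ± SD of n = 3 libraries, and changes are log2 fold changes with their standard error.

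The targeted locus came first. Mir23a, Mir27a and Mir24-2 lie between positions 84208518 and 84208921 on the plus strand of chromosome 8 (GRCm38), and all of them had 0 counts in all 12 libraries, so their levels check nothing about the labels. A pair of flanking transcripts, chosen after the values were seen, differed between the genotypes. Gm26532, a long noncoding RNA at 84208920 to 84209609, reached 3.24 ± 1.4 CPM in unchallenged wild-type and 0.251 ± 0.21 in unchallenged knockout libraries (log2 -3.60 ± 0.6, edgeR adjusted p = 0.00133). After challenge its levels were 3.51 ± 1 and 1.5 ± 1 CPM (log2 -1.23 ± 0.45, adjusted p = 0.0373). Challenged knockout replicate 3 stood at 2.68 CPM, inside the challenged wild-type range of 2.47 to 4.48 CPM and against its knockout label, while replicates 1 and 2 stood at 0.882 and 0.951 CPM. Gm37352, at 84200869 to 84203049, was higher in the knockout both without challenge (4.82 ± 1.8 against 59.5 ± 1.8 CPM) and after it (4.85 ± 2 against 36.9 ± 9 CPM). All 3 challenged knockout libraries held less of it (29.4 to 46.9 CPM) than the unchallenged ones (57.5 to 60.9 CPM), replicate 3 the least. The strand of the reads is not stated, so overlapping transcripts on opposite strands are not separated.

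**Figure D1:**
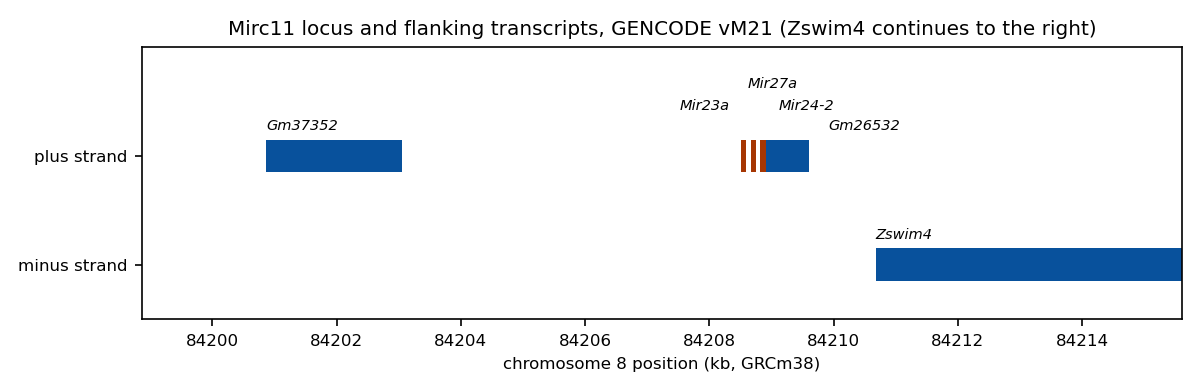
Map of the Mirc11 locus on chromosome 8 (position in kb, GRCm38), with the microRNA genes in brown and flanking transcripts in blue, by strand. Gm26532 starts within the last bases of Mir24-2, and Gm37352 lies upstream of Mir23a.

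Sex-linked transcripts separated the groups along with genotype. Xist, the noncoding RNA of the inactive X chromosome, measured 1620 ± 410 CPM in unchallenged wild-type, 1400 ± 170 in challenged wild-type and 0.72 ± 0.35 in unchallenged knockout libraries. In challenged knockout libraries it measured 738 ± 250 CPM, together with the Y-linked helicase Ddx3y at 55.4 ± 19 CPM. Ddx3y stood at 107 ± 25 CPM in unchallenged knockout and 0.0619 CPM in challenged wild-type libraries. Unchallenged wild-type replicate 4 carried Xist at 1180 CPM and 4 Y-linked transcripts with a sum of 115 CPM. Genotype was therefore confounded with sex, and so was challenge within knockout, where Xist went from at most 1.06 to at least 523 CPM. Of the 6 sex-linked transcripts, 1 rose and 2 fell in the unchallenged genotype comparison (adjusted over the list alone, 4 rose and 2 fell), with a median of 2.85, a mean of -0.36 and a camera adjusted p of 0.645. Rpl3-ps1, annotated as a processed copy of the ribosomal protein gene Rpl3, measured 310 ± 200 CPM in challenged knockout libraries and at most 0.327 CPM in any other library. Its reads are uncertain because Rpl3 has nearly the same sequence.

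**Figure D2:**
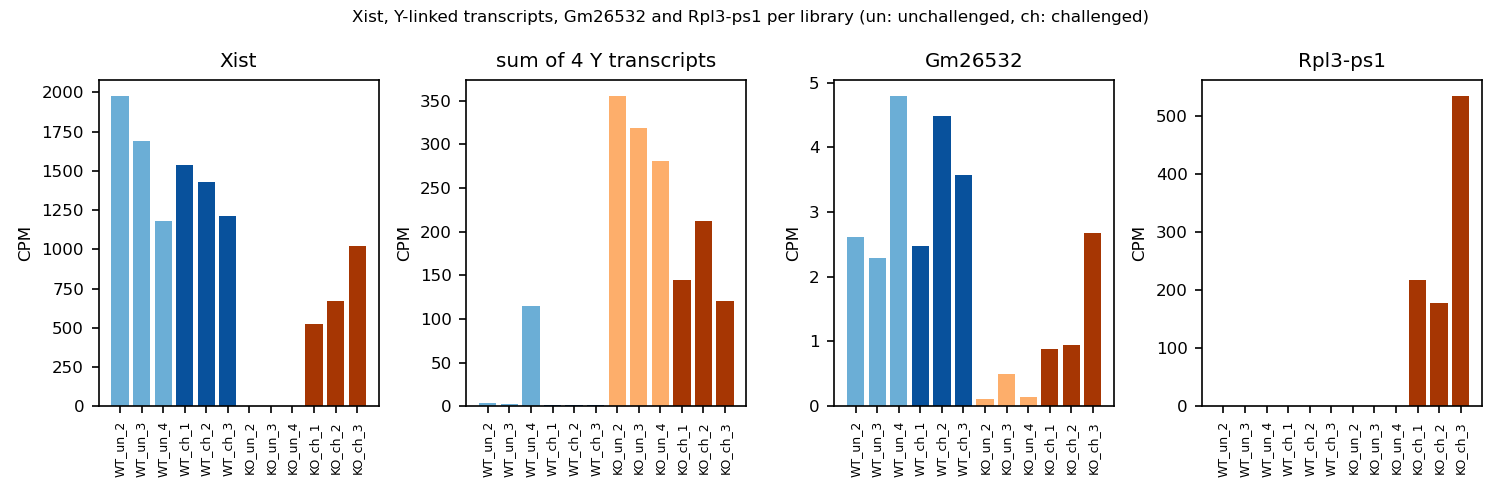
Xist, the sum of 4 Y-linked transcripts, Gm26532 and Rpl3-ps1 in CPM for each of the 12 libraries (bars, coloured by group; the number is the replicate). The challenged knockout libraries carry both Xist (523 to 1020 CPM) and Y-linked transcripts (121 to 212 CPM), and only they exceed 0.327 CPM for Rpl3-ps1.

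Between libraries, the Pearson correlation of log CPM across genes, which are not independent replicates, was 0.9844 to 0.991 within groups and 0.9114 to 0.9813 between groups. The first principal component held 61.3% of the variance and the second 12.7%. On the first component, challenged knockout libraries (2.4 to 12.3) lay between the unchallenged ones (-53.1 to -48.1 in wild-type, -51.1 to -50.4 in knockout) and the challenged wild-type ones (91.2 to 93.6). Haemoglobin transcripts made up 1.21 ± 0.098% of counts in unchallenged wild-type, 0.197 ± 0.029% in challenged wild-type, 3.74 ± 0.23% in unchallenged knockout and 2.24 ± 0.28% in challenged knockout libraries. Immunoglobulin transcripts made up 0.562 ± 0.06%, 1.02 ± 0.036%, 0.432 ± 0.021% and 0.753 ± 0.037% in the same order.

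In wild-type mice the challenge raised Gzmb, Ifng and Prf1 and lowered Ncr1, Klrk1 and Ccl5. Gzmb, which encodes the protease granzyme B, rose from 241 ± 18 to 1820 ± 34 CPM (log2 2.92 ± 0.07, edgeR adjusted p = 3.25e-13). Ifng, the main macrophage-activating cytokine gene of NK cells, rose from 93.4 ± 15 to 289 ± 8.9 CPM, and the pore-forming Prf1 from 627 ± 79 to 950 ± 11 CPM. The activating receptor genes Ncr1 and Klrk1 fell from 803 ± 55 to 203 ± 12 CPM and from 1060 ± 70 to 262 ± 8.3 CPM. The chemokine gene Ccl5 fell from 1670 ± 92 to 395 ± 15 CPM (log2 -2.08 ± 0.08, adjusted p = 7.04e-12). Of 16694 genes tested by edgeR's quasi-likelihood F test, 5411 rose and 5166 fell, which is 63.4%. At a change of at least 2-fold the numbers were 2258 and 1773.

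The 8 largest rises under the rule for naming genes included several with 0 counts in all 3 unchallenged wild-type libraries. Against a floor of 3 counts over the group, the interferon-induced chemokine Cxcl11 rose at least 202-fold, the cytokine Il22 at least 197-fold, the chemokine Ccl7 at least 183-fold and Spata31d1b at least 143-fold. The antibacterial lectin Reg3b rose from 0.221 ± 0.12 to 121 ± 14 CPM (log2 9.06 ± 0.23), and Nos2, which encodes inducible nitric oxide synthase, from 0.171 to 64.8 ± 11 CPM. Reg3a and the protease Mmp3 reached 35.4 ± 1.7 and 27 ± 3.1 CPM from levels near the floor. Whether the Reg transcripts came from NK cells or from other cells was not tested. The largest falls included red-cell genes: Slc4a1, the anion exchanger band 3, fell from 135 ± 25 to 2.35 ± 0.59 CPM (log2 -5.84 ± 0.22, edgeR adjusted p = 3.4e-10), with Rhd at -5.28 and Epb42 at -4.72. Btnl10, Cyp17a1, Cecr6, Rhpn1 and Clip4 changed by -6.02, -5.62, -5.09, -4.92 and -4.68 on the log2 scale. Challenged wild-type libraries together held 8 counts each of Btnl10 and Cyp17a1, so the sizes of these 2 are uncertain.

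Inflammatory genes and interferon targets moved as groups. Among 38 cytokine and chemokine genes, 31 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone (median 2.11, camera adjusted p = 5.04e-09). The median was 2.1 with Ccl7, Cxcl11 and Il22 set to their lower bounds. Cxcl10 rose by 6.42 ± 0.13, Cxcl9 by 5.96 and Il1b by 4.51, whereas Ccl3 fell by 0.48 ± 0.17, a call lost in 7 of the other fits, and Ccl4 did not pass (0.22, edgeR adjusted p = 0.153). Of 48 interferon-stimulated genes, 47 rose (47 adjusted over the list alone, median 2.54, camera adjusted p = 1.43e-23, adjusted p = 0.0857 with an estimated correlation), with Isg15 at 4.64 and Oasl2 at 4.55. All 33 genes of interferon-gamma induced GTPases and antigen presentation rose (33 adjusted over the list alone, camera adjusted p = 2.04e-15, adjusted p = 0.0857 with an estimated correlation), Gbp2 by 4.08 ± 0.09. For heat shock and protein folding, 23 of 24 rose (23 adjusted over the list alone, median 1.66, camera adjusted p = 8.3e-13), and Hspa8 went from 1070 ± 35 to 4960 ± 230 CPM.

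Transcripts of NK cell receptors and identity factors mostly fell. Whether they fell within NK cells or through a smaller share of NK cells was not tested, and markers of other cells also moved. Of 47 receptor and adaptor genes, 35 fell and 11 rose (the same adjusted over the list alone, median -1.29, camera adjusted p = 1e-05, adjusted p = 0.104 with an estimated correlation), with Klrb1c, which encodes NK1.1, at -2.60 ± 0.06. Of 34 transcription factor and maturation genes, 23 fell and 5 rose (23 and 6 adjusted over the list alone, camera adjusted p = 2.91e-05, adjusted p = 0.0857 with an estimated correlation). S1pr5, which guides exit from lymphoid tissue, fell by 3.78 ± 0.11, and Ccr7, a homing receptor for lymph nodes, rose by 2.45 ± 0.08. The cytotoxic granule list had 14 genes up and 5 down of 24 (the same adjusted over the list alone, median 0.57, camera adjusted p = 0.00899, adjusted p = 0.0857 with an estimated correlation), with Gzmc at 5 and Ctsw at -1.77.

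Signalling genes that the series title brings into question moved in both directions. Of 44 ubiquitin modifiers, 18 rose and 13 fell (the same adjusted over the list alone), with a median of 0.01 that turned to -0.1 under upper-quartile scaling, and a camera adjusted p of 0.642. Tnfaip3, which encodes the deubiquitinase A20, rose from 176 ± 38 to 492 ± 16 CPM (log2 1.48 ± 0.13, edgeR adjusted p = 3.46e-07). Usp18 rose by 4.17, the ligase gene Itch fell by 0.37 ± 0.1 (adjusted p = 0.00457) and Cblb did not pass (-0.02, adjusted p = 0.81). Of 39 genes from TRAF6 to NF-kB, 23 rose and 7 fell (24 and 7 adjusted over the list alone, median 0.35, camera adjusted p = 0.00127, adjusted p = 0.235 with an estimated correlation). The inhibitor gene Nfkbia rose from 111 ± 4.2 to 393 ± 18 CPM and Nfkb1 from 335 ± 6.6 to 468 ± 19 CPM. Traf6 (0.21 ± 0.07, adjusted p = 0.0119) and the deubiquitinase gene Cyld (0.21 ± 0.07, adjusted p = 0.0195) lost their calls under upper-quartile scaling (adjusted p = 0.178 and 0.225). Of 18 AP-1 factors, 15 rose (15 adjusted over the list alone, median 0.94, camera adjusted p = 8.1e-05, adjusted p = 0.0875 with an estimated correlation), with Batf2 at 6.43, Atf3 at 4.03 and Jun at 0.75. Fos rose by 0.31 ± 0.1 (adjusted p = 0.0126), a call lost under the same scaling (adjusted p = 0.0807). MAP kinase genes had 11 up and 6 down of 25 (the same adjusted over the list alone, camera adjusted p = 0.158), and immediate early genes 12 up and 3 down of 23 (the same adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.513 with an estimated correlation).

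Most growth and metabolism lists passed in wild-type at the preset correlation, and none of them with an estimated one. Of 46 cell-cycle genes, 45 rose (45 adjusted over the list alone, median 1.70, camera adjusted p = 1.69e-18, adjusted p = 0.0875 with an estimated correlation). Top2a, a topoisomerase of dividing cells, went from 102 ± 16 to 463 ± 35 CPM, and Mki67 from 214 ± 28 to 648 ± 56 CPM. Glycolysis had 15 up and 2 down of 20 (the same adjusted over the list alone, camera adjusted p = 8.21e-05, adjusted p = 0.268 with an estimated correlation), Pfkfb3 at 2.18. Oxidative phosphorylation had 32 up of 38 (32 up and 1 down adjusted over the list alone, median 0.38, camera adjusted p = 1.3e-05, adjusted p = 0.268 with an estimated correlation). Amino acid transport and the integrated stress response had 19 up of 23 (19 adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.0883 with an estimated correlation), Slc7a11 at 4.75 and Cebpb at 2.71. All 25 ribosome biogenesis genes rose (25 adjusted over the list alone, median 0.60, camera adjusted p = 3.09e-07, adjusted p = 0.0857 with an estimated correlation). Of 48 cytosolic ribosomal protein genes, 26 rose (26 adjusted over the list alone, median 0.23, camera adjusted p = 0.00262, adjusted p = 0.546 with an estimated correlation), and 17 rose and 1 fell under upper-quartile scaling. Cholesterol synthesis had 7 up and 4 down of 23 (the same adjusted over the list alone, camera adjusted p = 0.383), and the 13 mitochondrially encoded transcripts had 0 calls (0 adjusted over the list alone, camera adjusted p = 0.632). Apoptosis regulators had 18 up and 6 down of 27 (19 and 6 adjusted over the list alone, camera adjusted p = 0.000983, adjusted p = 0.0875 with an estimated correlation), and p53 targets 10 up and 6 down of 20 (the same adjusted over the list alone, camera adjusted p = 0.21), Cdkn1a at 4.27.

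Markers of other spleen cells moved beside these groups in wild-type. All 21 neutrophil markers rose (21 adjusted over the list alone, median 4.06, camera adjusted p = 2.33e-13, adjusted p = 0.0857 with an estimated correlation), with S100a8 from 10.6 ± 1.1 to 483 ± 72 CPM. Macrophage and monocyte markers had 17 up and 3 down of 23 (the same adjusted over the list alone, camera adjusted p = 9.02e-05, adjusted p = 0.268 with an estimated correlation), Mpeg1 at 2.40. Erythroid markers had 11 down and 2 up of 16 (the same adjusted over the list alone, median -2.15, camera adjusted p = 0.000665, adjusted p = 0.282 with an estimated correlation), Hba-a1, whose reads are not separable with certainty from its copy Hba-a2, falling from 2820 ± 230 to 487 ± 46 CPM. Platelet markers had 12 down and 2 up of 14 (the same adjusted over the list alone, camera adjusted p = 0.000144, adjusted p = 0.235 with an estimated correlation), Ppbp at -1.83. T cell markers had 13 down and 2 up of 17 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00272, adjusted p = 0.171 with an estimated correlation), and B cell markers 15 up and 2 down of 20 (the same adjusted over the list alone, camera adjusted p = 0.00817, adjusted p = 0.331 with an estimated correlation). Plasma cell markers had 7 up and 2 down of 11 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0403, adjusted p = 0.274 with an estimated correlation). Dendritic cell markers had 8 up and 5 down of 15 (the same adjusted over the list alone, camera adjusted p = 0.372), and mast cell and basophil markers 8 up and 1 down of 11 (the same adjusted over the list alone, camera adjusted p = 0.00564, adjusted p = 0.0857 with an estimated correlation). Markers of innate lymphoid cells of groups 2 and 3 had 9 up and 1 down of 12 (the same adjusted over the list alone, camera adjusted p = 0.00338, adjusted p = 0.0857 with an estimated correlation), and stromal and endothelial markers 13 up and 2 down of 17 (the same adjusted over the list alone, camera adjusted p = 0.00448, adjusted p = 0.0857 with an estimated correlation), Sparc at 2.51 and Vwf at -2.39.

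**Figure D3:**
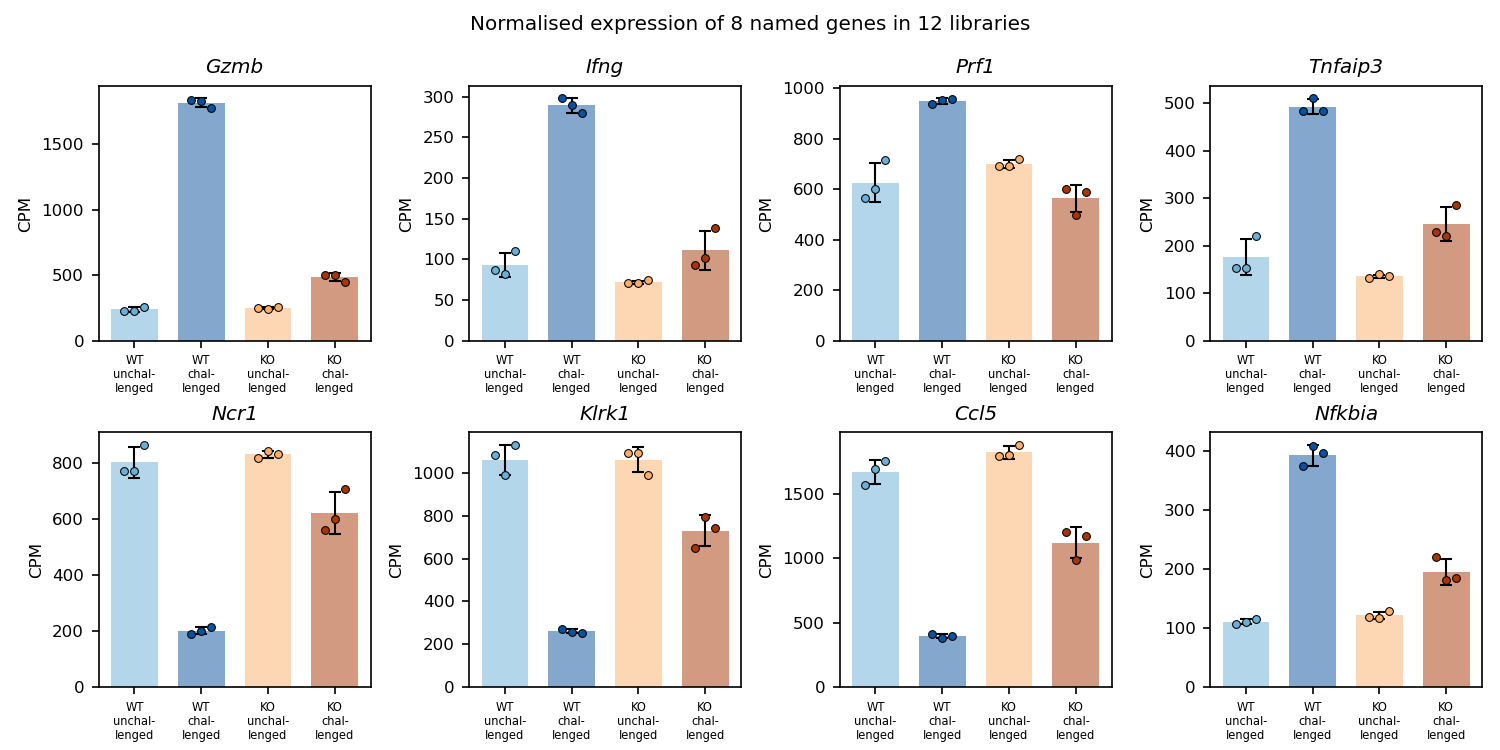
Normalised expression (CPM) of Gzmb, Ifng, Prf1, Tnfaip3, Ncr1, Klrk1, Ccl5 and Nfkbia in the 4 groups; bars are means, error bars SD and points the 3 libraries. Challenged wild-type libraries stand apart from the other groups for Gzmb (1820 CPM against 488 in challenged knockout) and for Ncr1 (203 against 623).

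Between challenged and unchallenged knockout libraries, which also differed in sex-linked transcripts, fewer genes changed than in wild-type. Gzmb rose to 488 ± 33 CPM in challenged knockout libraries (log2 0.97 ± 0.07, edgeR adjusted p = 6.91e-08). Ifng rose from 72.2 ± 1.9 to 111 ± 24 CPM (log2 0.62 ± 0.13, adjusted p = 0.00357). Prf1 fell from 702 ± 16 to 564 ± 55 CPM (log2 -0.32 ± 0.09, adjusted p = 0.0124), a call lost without challenged knockout replicate 2 (adjusted p = 0.0642). Ncr1 fell from 831 ± 12 to 623 ± 75 CPM, Klrk1 from 1060 ± 58 to 730 ± 73 CPM and Ccl5 from 1820 ± 50 to 1120 ± 120 CPM. edgeR called 2596 genes up and 1915 down, 27% of those tested, of which 733 and 93 changed at least 2-fold. Upper-quartile scaling called 2263 up and 2583 down.

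The largest rises in knockout were partly those of wild-type. Reg3b rose at least 143-fold from 0 counts to 7.1 ± 1.4 CPM. The acute-phase gene Saa3 rose from 0.315 to 43.8 ± 11 CPM (log2 7.10 ± 0.31, edgeR adjusted p = 6.13e-09), the neutrophil attractant Cxcl2 from 1.08 to 72.5 ± 15 CPM and the GTPase gene Gbp2b from 0.156 to 11.5 ± 2 CPM. The heat shock genes Hspa1a and Hspa1b rose by 5.92 ± 0.25 and 5.84 ± 0.21, with the split between these near-identical copies uncertain. Xist (log2 10.04 ± 0.45) and Rpl3-ps1 (11.77 ± 0.99) also ranked among the top. The largest falls were pancreatic enzyme transcripts: Sycn fell from 5.76 ± 0.54 to 1.89 ± 0.75 CPM (log2 -1.59 ± 0.21, adjusted p = 5.45e-05), and the amylase copies Amy2a2, Amy2a3 and Amy2a4, whose reads are not separable with certainty, fell by 1.48. Pnlip, Cel, Clps and Cela2a changed by -1.40, -1.35, -1.33 and -1.30, calls that were each lost in a fit with only the 6 libraries compared. Of 19 pancreatic transcripts in a list made after the values were seen, 17 fell in knockout (18 adjusted over the list alone) and 11 rose in wild-type, with medians of -1.25 and 0.91. Camera on that list, outside the adjustment over lists, gave p = 1.05e-08 in knockout and 0.0225 in wild-type, and 0.177 and 0.571 with an estimated correlation. Since the list was made from these data, these p-values are no independent test of its change.

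Interferon targets rose in knockout too. Of 48 interferon-stimulated genes, 45 rose (46 adjusted over the list alone, median 1.40, camera adjusted p = 3.26e-38, adjusted p = 0.0511 with an estimated correlation); Isg15 went from 28 ± 2.1 to 114 ± 20 CPM and Ifit1 from 8.38 ± 0.81 to 61.5 ± 7.3 CPM. The GTPase and antigen presentation list had 30 up of 33 (31 adjusted over the list alone, camera adjusted p = 1.06e-20, adjusted p = 0.0658 with an estimated correlation), Gbp2 at 2.63. Cytokines and chemokines had 23 up and 5 down of 38 (25 and 5 adjusted over the list alone, median 0.62, the same with Ccl7 at its bound; camera adjusted p = 3.52e-10), Cxcl10 at 3.84, while Ccl3 (0.48, edgeR adjusted p = 0.0645) and Ccl4 (0.35, adjusted p = 0.0682) did not pass. Heat shock genes had 22 up and 1 down of 24 (23 and 1 adjusted over the list alone, camera adjusted p = 1.29e-16), and cell-cycle genes 41 up of 46 (43 adjusted over the list alone, median 0.58, camera adjusted p = 3.01e-18, adjusted p = 0.118 with an estimated correlation). Ribosome biogenesis had 22 up of 25 (22 adjusted over the list alone, camera adjusted p = 4.6e-12, adjusted p = 0.0511 with an estimated correlation), Nop58 at 0.60. NK receptors had 22 down and 6 up of 47 (27 and 7 adjusted over the list alone, median -0.33, camera adjusted p = 7.69e-06, adjusted p = 0.118 with an estimated correlation), Klrb1c at -0.64, whereas the inhibitory receptor gene Pdcd1 rose by 3.13. The cytotoxic list had 10 up and 8 down of 24 (10 and 9 adjusted over the list alone, median 0, below 0 under the other scalings; camera adjusted p = 0.646).

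Of the signalling lists in knockout, AP-1 factors and immediate early genes passed at the preset correlation. AP-1 factors had 10 up of 18 (10 adjusted over the list alone, median 0.59, camera adjusted p = 1.63e-05, adjusted p = 0.0929 with an estimated correlation), Jun by 0.88 ± 0.09 and Fos by 0.85 ± 0.1. Immediate early genes had 11 up of 23 (12 up and 1 down adjusted over the list alone, camera adjusted p = 8.38e-05, adjusted p = 0.304 with an estimated correlation), with a median of 0.32 against 0.31 in wild-type. MAP kinase genes had 6 up and 2 down of 25 (7 and 2 adjusted over the list alone, camera adjusted p = 0.481). TRAF6 to NF-kB genes had 9 up and 1 down of 39 (the same adjusted over the list alone), with a median of 0.04 that was -0.01 under upper-quartile scaling and a camera adjusted p of 0.318. Nfkbia rose from 122 ± 6.3 to 195 ± 22 CPM and Tnfaip3 from 136 ± 3.4 to 245 ± 36 CPM, while Nfkb1 (-0.06, edgeR adjusted p = 0.56), Traf6 (-0.06, adjusted p = 0.6), Cyld (0.08, adjusted p = 0.472) and Itch (0.05, adjusted p = 0.748) did not pass. Ubiquitin modifiers had 6 up and 6 down of 44 (6 and 7 adjusted over the list alone, camera adjusted p = 0.646). Markers of other cells moved as well: neutrophil markers had 18 up and 3 down of 21 (the same adjusted over the list alone, camera adjusted p = 1.19e-10, adjusted p = 0.118 with an estimated correlation), B cell markers 17 up of 20 (17 adjusted over the list alone, camera adjusted p = 2.69e-11, adjusted p = 0.0728 with an estimated correlation). T cell markers had 11 up and 2 down of 17, against 2 up and 13 down in wild-type (12 and 2 adjusted over the list alone, camera adjusted p = 0.000202, adjusted p = 0.118 with an estimated correlation). Macrophage and monocyte markers had 15 up and 2 down of 23 (16 and 2 adjusted over the list alone, camera adjusted p = 9.86e-08, adjusted p = 0.154 with an estimated correlation). Plasma cell markers had 10 up of 11 (10 adjusted over the list alone, camera adjusted p = 3.17e-06, adjusted p = 0.0662 with an estimated correlation), and erythroid markers 11 down and 1 up of 16 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000156, adjusted p = 0.304 with an estimated correlation), Hba-a1 at -0.75.

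Without challenge, most of the NK effector genes examined did not pass, and genes of other blood cells differed. Gzmb (0.05 ± 0.07, edgeR adjusted p = 0.76), Prf1 (0.16, adjusted p = 0.292), Ifng (-0.37, adjusted p = 0.0992), Ncr1 (0.05, adjusted p = 0.8), Klrk1 (-0.01, adjusted p = 0.971) and Ccl5 (0.13, adjusted p = 0.349) did not pass. Granule proteins of neutrophils were higher in knockout: Ltf measured 74.5 ± 3.6 against 3.03 ± 0.87 CPM (log2 4.62 ± 0.23, adjusted p = 1e-07), Camp 26.6 ± 1.8 against 1.47 ± 0.42, Ngp 78.2 ± 3.2 against 4.69 ± 0.25 and Lcn2 31.4 ± 1.5 against 1.91 ± 0.62. Cd177, S100a8, Mpo and S100a9 completed the top, at 3.04, 3.01, 2.98 and 2.85. Xist was the largest fall (-11.17 ± 0.46), followed by Lzts1, a tumour suppressor gene (13.2 ± 1.2 to 1.32 ± 0.29 CPM), Ptprk (-2.41), Fhl1 (-2.07), Draxin (-2.06), Mfap3l (-2.04), Peg10 (-2.02) and the platelet chemokine gene Ppbp (-1.98 ± 0.13). edgeR called 1109 genes up and 846 down, 11.7% of those tested, of which 454 and 223 at least 2-fold.

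Several lists of other cell types passed in this comparison also with an estimated correlation. Neutrophil markers had 19 up of 21 (19 adjusted over the list alone, median 2.73, camera adjusted p = 4.35e-30), and erythroid markers 14 up of 16 (14 adjusted over the list alone, median 1.64, camera adjusted p = 1.29e-20), with Hba-a1 at 9210 ± 530 against 2820 ± 230 CPM and Slc4a1 at 723 ± 30 against 135 ± 25 CPM. Mast cell and basophil markers had 8 up and 2 down of 11 (the same adjusted over the list alone, camera adjusted p = 1.13e-07), the basophil protease gene Mcpt8 at 2.84. Platelet markers had 13 down of 14 (14 adjusted over the list alone, median -1.22, camera adjusted p = 8.6e-17), B cell markers 19 down of 20 (19 adjusted over the list alone, median -0.53, camera adjusted p = 9.9e-16), Cd79a at -0.56, and T cell markers 9 down of 17 (13 adjusted over the list alone, camera adjusted p = 2.04e-09), Cd3g at -0.74. Cell-cycle genes had 29 up of 46 (32 adjusted over the list alone, median 0.51, camera adjusted p = 3.11e-20, adjusted p = 0.148 with an estimated correlation), with Mki67 at 402 ± 12 against 214 ± 28 CPM.

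Without challenge no signalling list passed camera. The mixed fry test, which asks for change in either direction, passed for all 5, but it passed for 31 of all 34 lists here. It therefore does not set the signalling lists apart. Ubiquitin modifiers had 1 up (March8, 0.71) and 1 down of 44 (1 and 0 adjusted over the list alone, camera adjusted p = 0.336). TRAF6 to NF-kB genes had 4 down of 39 (3 adjusted over the list alone, camera adjusted p = 0.271). MAP kinase genes had 5 down and 1 up of 25 (the same adjusted over the list alone, camera adjusted p = 0.0803, directional fry adjusted p = 0.00837), and immediate early genes 4 down and 2 up of 23 (the same adjusted over the list alone, camera adjusted p = 0.414). AP-1 factors had 3 up and 3 down of 18 (the same adjusted over the list alone, camera adjusted p = 0.887), with Fos at 188 ± 5.5 against 335 ± 14 CPM (log2 -0.83 ± 0.1, edgeR adjusted p = 3.14e-05) and Jun at 162 ± 0.84 against 253 ± 13 CPM. Tnfaip3 (-0.37, adjusted p = 0.0909), Cblb (-0.11, adjusted p = 0.254), Itch (-0.21, adjusted p = 0.236), Cyld (-0.11, adjusted p = 0.457) and Traf6 (0.05, adjusted p = 0.736) did not pass. Tnf (-0.42), Csf2 (-0.72), Xcl1 (-0.21) and Ccl3 (-0.68) were lower, with calls that leaving out single libraries removed. Cytokines and chemokines had 6 up and 6 down of 38 (6 and 8 adjusted over the list alone, median 0.06, and 0.01 with members at 0 set to their bounds; camera adjusted p = 0.414). NK receptors had 10 down and 2 up of 47 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0267, adjusted p = 0.503 with an estimated correlation). The interferon-gamma list had 10 down of 33 (10 adjusted over the list alone, camera adjusted p = 0.000151, adjusted p = 0.456 with an estimated correlation), Gbp6 at -1.15, while 4 interferon-stimulated genes were higher and 6 lower of 48 (4 and 7 adjusted over the list alone, camera adjusted p = 0.0809), Isg15 at 0.96.

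After challenge the genotypes differed at many effector and receptor genes. Gzmb measured 488 ± 33 CPM in knockout against 1820 ± 34 in wild-type libraries (log2 -1.90 ± 0.07, edgeR adjusted p = 3.4e-11), Ifng 111 ± 24 against 289 ± 8.9 (log2 -1.38 ± 0.13, adjusted p = 1.76e-06), Prf1 564 ± 55 against 950 ± 11 and Tnf 21.7 ± 2.6 against 52.5 ± 3.7. Receptor genes were higher in knockout: Ncr1 623 ± 75 against 203 ± 12 CPM, and Klrk1 730 ± 73 against 262 ± 8.3 CPM. Whether the share of NK cells differed between these libraries was not tested. Ccl5 was higher as well (1120 ± 120 against 395 ± 15 CPM), while Csf2 and Xcl1 were lower (-1.38 and -0.50) and Ccl3 (0.28, adjusted p = 0.211) and Ccl4 (-0.08, adjusted p = 0.645) did not pass. edgeR called 3792 genes up and 4332 down, 48.7% of those tested, of which 1135 and 1038 at least 2-fold; upper-quartile scaling gave 4606 up and 3520 down. In this comparison and the unchallenged one, 426 genes were called higher in both (252 expected if independent) and 359 lower in both (220 expected). In opposite directions, 355 were higher without challenge and lower after it (288 expected), and 197 the other way (192 expected).

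The largest differences after challenge included red-cell genes. Slc4a1 measured 445 ± 84 against 2.35 ± 0.59 CPM (log2 7.56 ± 0.23, edgeR adjusted p = 2.29e-10), Epb42 42 ± 7.4 against 0.465, and Rhd 31.4 ± 5 against 0.264. Btnl10 measured 26.3 ± 5.6 against 0.123 CPM, and Apol8 differed by 6.88. Both sizes are uncertain, since challenged wild-type libraries together held 8 and 4 counts of them. Rpl3-ps1, Ddx3y and Eif2s3y were also higher, the last with a call lost in a fit with replicate blocks (adjusted p = 0.0547). Genes of secreted Reg lectins were among those lower in knockout: Reg3b measured 7.1 ± 1.4 against 121 ± 14 CPM (log2 -4.09 ± 0.15), Reg3a 2.56 ± 0.55 against 35.4 ± 1.7 and Reg3d 0.366 ± 0.2 against 9.26 ± 1.6, with Reg3g, Reg1 and Reg2 at -4.00, -3.99 and -3.94. Spata31d1b and the mucosal glycoprotein gene Dmbt1 were at -3.80 and -3.91. The pancreatic transcripts listed after the values were seen were lower too, 18 of 19 (19 adjusted over the list alone, median -2.84, camera p = 1.02e-10 outside the adjustment over lists, 0.133 with an estimated correlation). As the list was made from these data, that p-value is no independent test. Whether the Reg and pancreatic transcripts came from NK cells or from other cells was not tested. Erythroid markers had 14 up and 1 down of 16 (the same adjusted over the list alone, median 3.00, camera adjusted p = 7.11e-11, adjusted p = 0.119 with an estimated correlation). Neutrophil markers had 14 down and 5 up of 21 (15 and 5 adjusted over the list alone, camera adjusted p = 0.0091, adjusted p = 0.442 with an estimated correlation), and platelet markers 9 up and 2 down of 14 (the same adjusted over the list alone, camera adjusted p = 0.00611, adjusted p = 0.366 with an estimated correlation). T cell markers had 14 up and 2 down of 17 (the same adjusted over the list alone, camera adjusted p = 0.000301, adjusted p = 0.119 with an estimated correlation). Dendritic cell markers had 6 up and 7 down of 15 (the same adjusted over the list alone, camera adjusted p = 0.846), their median (-0.26) and mean (0.44) differing in sign.

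Of the signalling lists after challenge, those of NF-kB, AP-1 and MAP kinases passed at the preset correlation and none of them with an estimated one. TRAF6 to NF-kB genes had 25 down and 1 up of 39 (26 and 3 adjusted over the list alone, median -0.30, camera adjusted p = 6.05e-06, adjusted p = 0.119 with an estimated correlation), Nfkb2 at -1.42, Traf1 at -1.24, Nfkbia at -1.01 and Nfkb1 at -0.60. AP-1 factors had 13 down of 18 (13 adjusted over the list alone, median -0.44, camera adjusted p = 0.000797, adjusted p = 0.143 with an estimated correlation), Atf3 at -1.90, Fosl2 at -0.99 and Jun at -0.51. MAP kinase genes had 15 down and 4 up of 25 (16 and 4 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.174 with an estimated correlation). Immediate early genes did not pass (11 down and 5 up of 23, the same adjusted over the list alone, camera adjusted p = 0.131). Nor did ubiquitin modifiers, with 18 down and 9 up of 44 (the same adjusted over the list alone, camera adjusted p = 0.196) and a median of -0.07 that was 0 under upper-quartile scaling. Tnfaip3 measured 245 ± 36 against 492 ± 16 CPM (log2 -1 ± 0.13, edgeR adjusted p = 2.68e-05), Usp18 differed by -1.92 and Cblb by -0.23, and the ligase gene Cbl was higher by 0.83 and March8 by 1.18. Itch did not pass (0.21, adjusted p = 0.0888). Traf6 (-0.22, adjusted p = 0.0151), Cyld (-0.24, adjusted p = 0.0136) and Fos (-0.28, adjusted p = 0.0262) lost their calls under upper-quartile scaling (adjusted p = 0.0994, 0.0825 and 0.0877).

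Effector and growth lists differed along with them. Cytokines and chemokines had 28 down and 4 up of 38 (29 and 4 adjusted over the list alone, median -1.17, camera adjusted p = 3.54e-07), Cxcl10 at -2.27 and Lif at -2.22. Markers of macrophages and monocytes, which also make cytokines, had 16 down and 5 up of 23 (the same adjusted over the list alone, camera adjusted p = 0.0405, adjusted p = 0.519 with an estimated correlation). Interferon-stimulated genes had 47 down of 48 (47 adjusted over the list alone, median -1.22, camera adjusted p = 3.07e-23, adjusted p = 0.0994 with an estimated correlation), Isg15 at 114 ± 20 against 360 ± 21 CPM. All 33 interferon-gamma list genes were lower (33 adjusted over the list alone, camera adjusted p = 1.9e-16, adjusted p = 0.0994 with an estimated correlation), Cd274, which encodes PD-L1, at -1.84. Heat shock genes had 23 down of 24 (23 adjusted over the list alone, camera adjusted p = 1.01e-13), and cell-cycle genes 43 down of 46 (43 adjusted over the list alone, camera adjusted p = 1e-11, adjusted p = 0.174 with an estimated correlation), Top2a at 242 ± 14 against 463 ± 35 CPM. The cytotoxic list had 16 down and 3 up of 24 (the same adjusted over the list alone, camera adjusted p = 0.000271, adjusted p = 0.0577 with an estimated correlation), Gzmc at -2.79. NK receptors had 31 up and 12 down of 47 (32 and 12 adjusted over the list alone, median 0.59, camera adjusted p = 0.000271, adjusted p = 0.174 with an estimated correlation), Klrb1c at 1.94. Maturation genes had 22 up and 7 down of 34 (the same adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.0994 with an estimated correlation), S1pr5 at 3.33. Glycolysis had 15 down and 2 up of 20 (the same adjusted over the list alone, camera adjusted p = 4.65e-05, adjusted p = 0.274 with an estimated correlation), Pfkfb3 at -1.62.

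**Figure D4:**
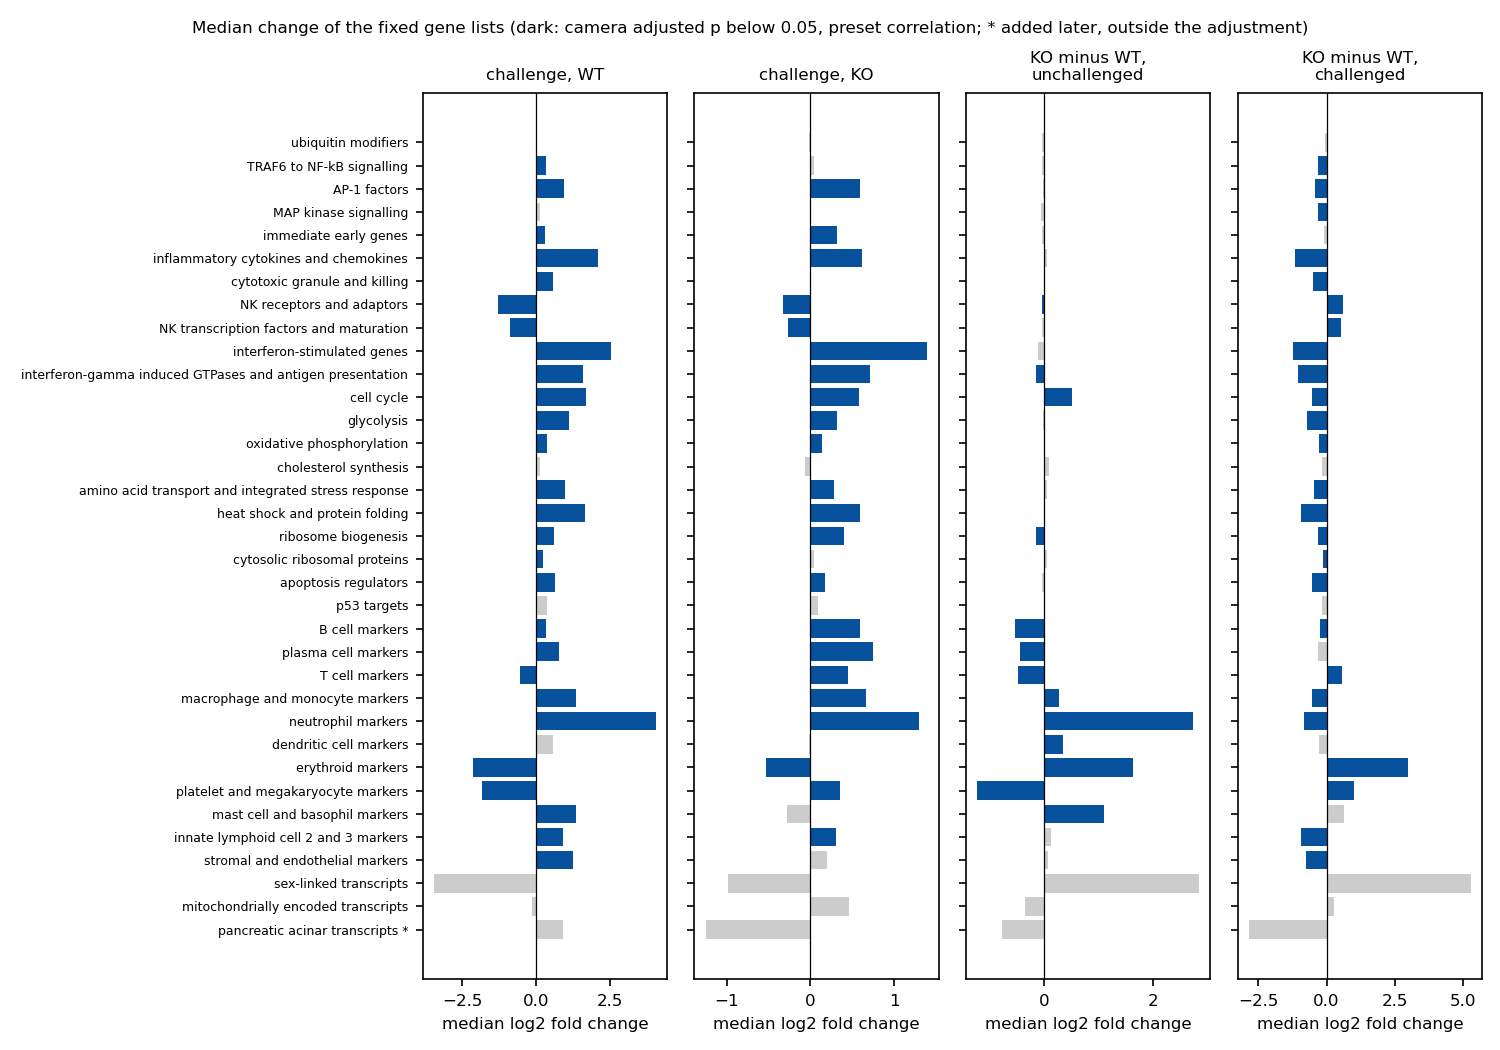
Median log2 fold change of the tested members of each fixed gene list in 4 comparisons (bars; dark bars have a camera adjusted p below 0.05 at the preset correlation, and each panel has its own scale). The starred pancreatic list was added after the values were seen and stands outside the adjustment, so its bars are not dark.

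The response to challenge was compared between genotypes directly, through the interaction term. Knockout minus wild-type response was -1.95 ± 0.1 for Gzmb (edgeR adjusted p = 4.65e-09), -1.01 ± 0.18 for Ifng (adjusted p = 0.000903), -0.91 ± 0.12 for Prf1 and -1.15 ± 0.11 for Nfkbia. It was 1.56 ± 0.12 for Ncr1, 1.49 ± 0.11 for Klrk1 and 1.37 ± 0.11 for Ccl5, genes that fell less in knockout. Fos (0.55 ± 0.14, adjusted p = 0.00598) rose more in knockout, from a lower level. The terms for Cblb (-0.12, adjusted p = 0.227), Cyld (-0.13, adjusted p = 0.345), Jun (0.13, adjusted p = 0.477), Ccl4 (0.12, adjusted p = 0.641) and Csf2 (-0.66, adjusted p = 0.0639) did not pass. Tnfaip3 (-0.63 ± 0.18, adjusted p = 0.0156), Traf6 (-0.27, adjusted p = 0.0391), Itch (0.42, adjusted p = 0.0298) and Xcl1 (-0.29, adjusted p = 0.0209) passed, with calls that other fits removed. The term was positive for 2791 genes and negative for 3085, together 35.2% of those tested, a balance that upper-quartile scaling turned to 3314 positive and 2680 negative.

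Across the 4031 genes called in wild-type with at least a 2-fold change, the knockout change had the same sign for 88.7% and was smaller for 98.1%. The slope of knockout on wild-type changes through 0 was 0.39, with 0.482 over raised and 0.182 over lowered genes. Choosing genes by their wild-type change favours a larger change there. Of 1327 genes chosen on the mean of both responses, a comparison added after the values were seen, 97.1% changed less in knockout, against 50% under equal responses, with a ratio of root mean square changes of 0.589. Of the 826 genes called in knockout at 2-fold, a choice that favours knockout, 74.3% changed less there. Of the 5876 genes with a called interaction, 5592 (95.2%) were called in wild-type with a smaller change in knockout, counts that share the wild-type libraries with the interaction term. Challenge raised 2352 genes in both genotypes (841 expected if independent) and lowered 1648 in both (593 expected). By list, cytokines called at 2-fold in wild-type (26 genes) had medians of 3.7 in wild-type and 1.56 in knockout, and interferon-stimulated genes (43 genes) 2.66 and 1.5. NK receptors (31 genes) had -1.54 and -0.43, with 30 of the interaction terms called, Il18rap at 1.51 among them.

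Among lists tested on the interaction term, heat shock genes had 20 negative of 24 (20 adjusted over the list alone, camera adjusted p = 4.95e-13) and cytokines 19 negative and 4 positive of 38 (23 and 4 adjusted over the list alone, camera adjusted p = 1.26e-07). Macrophage and monocyte markers had 12 negative and 3 positive of 23 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.345 with an estimated correlation). All 21 neutrophil markers were negative (21 adjusted over the list alone, camera adjusted p = 1.03e-16, adjusted p = 0.0666 with an estimated correlation). TRAF6 to NF-kB genes had 22 negative and 1 positive of 39 (23 and 3 adjusted over the list alone, camera adjusted p = 7.1e-05, adjusted p = 0.138 with an estimated correlation), Nfkb1 at -0.54. AP-1 factors had 10 negative and 1 positive of 18 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0039, adjusted p = 0.195 with an estimated correlation), Fosl2 at -1.31. Immediate early genes had 6 negative and 4 positive of 23 (the same adjusted over the list alone, median 0.06, camera adjusted p = 0.469), and MAP kinase genes 8 negative and 4 positive of 25 (the same adjusted over the list alone, camera adjusted p = 0.36). Neither list passed. Ubiquitin modifiers had 16 negative and 10 positive of 44 (the same adjusted over the list alone, camera adjusted p = 0.36), with a median of -0.05 that was 0.01 under upper-quartile scaling. NK receptors had 31 positive and 8 negative of 47 (32 and 9 adjusted over the list alone, camera adjusted p = 6.01e-06, adjusted p = 0.101 with an estimated correlation), Klrb1c at 1.96. T cell markers moved the same way, with 14 positive and 2 negative of 17 (median 1.01), as did erythroid markers, with 10 positive and 2 negative of 16 (median 1.47).

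**Figure D5:**
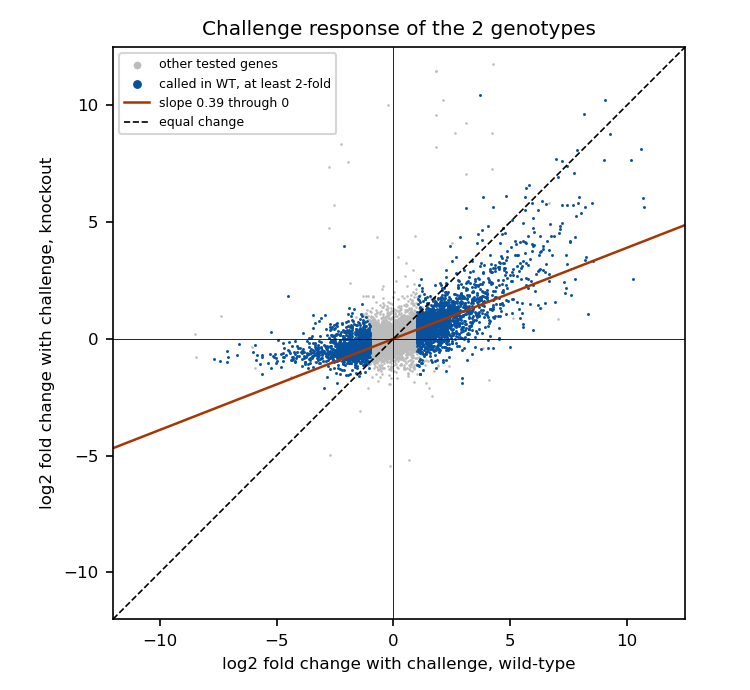
Log2 fold change with challenge in knockout (vertical) against wild-type (horizontal) for each tested gene; blue points were called in wild-type with at least a 2-fold change. The fitted line has a slope of 0.39 and the dashed line marks equal change.

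Averaged over both treatments, edgeR called 3034 genes higher and 3184 lower in knockout, 37.2% of those tested, and 3702 higher and 2526 lower under upper-quartile scaling. The Y-linked Ddx3y (6.44 ± 1.28, adjusted p = 0.00444) and Eif2s3y (5.91) were among the largest values. Slc4a1 (4.99 ± 0.14, adjusted p = 2.31e-10), Btnl10 (4.93), Apol8 (4.67), Rhd (4.55) and Epb42 (4.42) were higher. Challenged wild-type libraries together held 4 counts of Ddx3y, 6 of Eif2s3y, 8 of Btnl10 and 4 of Apol8, so these sizes are uncertain. Lower genes were Xist (-6.04 ± 0.27), Lzts1 (-2.66 ± 0.18) and Dmbt1 (-2.40), and Reg3b, Reg3g and Reg3a, whose averages have no exact size because unchallenged knockout libraries held 0 counts of them. Ceacam15, also at 0 counts there (adjusted p = 0.0101), lost its call without unchallenged wild-type replicate 2 (adjusted p = 1), and Amy2a5 (-2.89, adjusted p = 0.0332) in 10 of the other fits. TRAF6 to NF-kB genes had 22 lower and 1 higher of 39 (23 and 1 adjusted over the list alone, camera adjusted p = 2.6e-06, adjusted p = 0.113 with an estimated correlation). Heat shock genes had 23 lower of 24 (23 adjusted over the list alone, camera adjusted p = 8.31e-14). Markers of other cells differed as well: erythroid markers had 14 higher of 16, and neutrophil markers 14 higher and 2 lower of 21. Mast cell and basophil markers had 9 higher and 2 lower of 11, and B cell markers 1 higher and 16 lower of 20.

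Genes with predicted sites of the deleted microRNAs moved little. Of the tested genes, 13543 (81.1%) had an annotated 3' UTR, and 2321, 2572 and 2839 of them held a site for miR-23a (AATGTGA), miR-27a (ACTGTGA) and miR-24 (CTGAGCC), against 5885 without any. In knockout minus wild-type, the median shift of genes with a site over genes without was 0.012, 0.043 and 0.026 for miR-23a without challenge, after it and averaged. It was 0.019, 0.029 and 0.02 for miR-27a and 0.031, 0.011 and 0.023 for miR-24. Against 10000 random gene lists matched on UTR length and expression, 8 of 9 adjusted resampling p-values lay below 0.05 (0.0006 to 0.00293), and that of miR-24 after challenge was 0.239. None of the 9 shifts (0) lay above those of all 100 shuffled seeds. Genes are not independent replicates, and camera on the same lists gave p from 0.299 to 0.816.

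Genes near the locus were called more often in some comparisons. Within 10 Mb of Mirc11, 27 of 143 tested genes (18.9%) were called without challenge against 11.7% of the other tested genes (odds ratio 1.76, two-sided Fisher's exact p = 0.0123, adjusted p = 0.0185 over 3 comparisons). After challenge 72 of 143 (50.3%) were called (odds ratio 1.07, exact p = 0.737), and averaged over treatments 72 of 143 (odds ratio 1.72, exact p = 0.00167, adjusted p = 0.00501). Without challenge the share was 22.2% within 2 Mb (18 of 81) and 18.5% within 25 Mb (81 of 437), so it was not particular to the 10 Mb window. Neighbouring genes are not independent, which Fisher's exact test assumes.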

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

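The tests of explanations and the other splits of the libraries in this part were chosen only after the result was seen. Every value here appears because the challenge response differed between the genotypes, as tested by the interaction term of the fit (knockout minus wild-type response).

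The difference was called for 5876 genes and, by camera, for 25 of 34 gene lists, of which 2 kept their call with an estimated correlation. Its largest positive values were those of Xist (10.25), the red-cell genes Slc4a1 (5.14) and Rhd (4.63), Btnl10 (5.46), Apol8 (4.41), the steroid enzyme gene Cyp17a1 (4.92), Rhpn1 (4.87) and the dendritic-cell lectin gene Cd209a (4.61). Among its largest negative values were those of Lcn2 (-5.18), Npr1 (-4.93), Reg3d (-4.77) and Mrgpra2b (-4.83), a receptor gene whose reads are not separable with certainty from those of Mrgpra2a. The fitted values of Spata31d1b (-7.69), Flrt3 (-5.73), Nrg1 (-5.23) and Mrgpra2a (-4.76) have no exact size or rank, since unchallenged wild-type libraries held 0, 3, 1 and 1 counts of them. The same libraries held 4 counts of Mrgpra2b and 7 of Reg3d. Challenged wild-type libraries held 4 of Apol8, 5 of Cd209a and 8 each of Btnl10 and Cyp17a1, so the sizes and ranks of these genes are uncertain too. Flrt3 lost its call without unchallenged knockout replicate 3 (adjusted p = 0.0592).

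Among the genes fixed in advance, the term was negative for Gzmb (-1.95), Nfkbia (-1.15), Ifng (-1.01), Prf1 (-0.91), Tnf (-0.86), Tnfaip3 (-0.63), Nfkb1 (-0.54), Xcl1 (-0.29) and Traf6 (-0.27). It was positive for Ncr1 (1.56), Klrk1 (1.49), Ccl5 (1.37), Ccl3 (0.96), Fos (0.55) and Itch (0.42). Other settings removed the calls of Tnfaip3 (adjusted p up to 0.0748), Itch (up to 0.0821), Xcl1 (up to 0.0755) and Traf6 (up to 0.122). Of 100 splits drawn from 200 that keep the treatments apart, 2 gave at least the real 5876 genes, the real split among them. A chance assignment of libraries is excluded at a share of 0.05 only if the libraries are independent, which the labels do not say. The splits regroup the genotypes, so they test for any genotype difference and cannot test the interaction itself. The highest other split, with 6218, exchanges the genotype labels of the challenged libraries and so turns the interaction into the average difference between genotypes.

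The first pattern weighed is the smaller challenge response of knockout libraries. Scaling between libraries was weighed first. The knockout to wild-type ratio of root mean square changes was at most 0.592 under 3 scalings, over genes chosen on the mean of both responses. Upper-quartile scaling, the furthest from TMM, moved the median gene by only -0.11 in wild-type and -0.05 in knockout. The choice among these scalings therefore does not account for the smaller response, while a larger error of scaling was not tested. Another explanation is a single proportion of unresponding RNA in each challenged knockout library, the rest responding as wild-type. Raised genes kept 0.27 of the wild-type change in CPM (0.23 to 0.31 over the libraries) and lowered genes 0.39 (0.38 to 0.43). Over genes chosen on the mean of both responses the values were 0.3 and 0.45. This gap argues against such a mixture as the whole cause only where unchallenged levels are equal, and 1955 genes differed between the unchallenged genotypes. Log2 slopes were 0.482 over raised and 0.182 over lowered genes, an order that adding unresponding RNA would also give. A mixture as part or whole of the cause, an effect of genotype, of sex, of the share of NK cells, or of a different dose or course of infection stay open, and the design does not separate them.

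The second pattern is the mixed identity of the challenged knockout libraries. Male and female mice in the same libraries may explain its sex-linked transcripts: Xist stood at 0.37, 0.48 and 0.73 of its level in challenged wild-type and Y-linked transcripts at 0.46, 0.67 and 0.38 of theirs in unchallenged knockout, with sums of 0.83, 1.15 and 1.11. RNA of the wild-type libraries of this series mixed in is argued against only as the source of Rpl3-ps1, which reached at least 177 CPM there and at most 0.327 CPM elsewhere, and for which reads of Rpl3 assigned to this processed copy could account, since the sum of both was 1178 to 1377 CPM against 1198 to 1477 for Rpl3 in the other 9 libraries. As the source of the sex-linked and flanking transcripts, such a mixture cannot be told apart: replicate 3 had the most Xist (1020 CPM) and Gm26532 (2.68) and the least Gm37352 (29.4), and the wild-type shares implied by these and the Y-linked transcripts overlapped in 1 of 3 libraries, this replicate itself (0.51 to 0.58 by Gm37352), over ranges set by few libraries and low counts of Gm26532. A sequence variant of some of the mice, or RNA of mice outside this series, stays open as untested.

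The third pattern is the higher level of erythroid and neutrophil transcripts in unchallenged knockout libraries. A lower share of NK cells with all other cell types raised alike is argued against, because platelet markers had a median of -1.22. More erythroid cells and more neutrophils or their precursors stay open as untested, since the markers that would show them are the pattern itself (Hba-a1 at 9210 against 2820 CPM, S100a9 at 139 against 19.4 CPM). Negative selection would remove such cells, and whether their residue differed through genotype, sex or handling was not tested.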

How the results depend on the processing

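Removal of genes on X and Y and of markers of other cells were alternatives chosen after the values were seen, and all others were planned. Depth limits genes near the floor, at 0.042 to 0.0561 CPM per count, and 3 libraries per group limit small changes. The comparisons of genotype and of challenge within knockout also differ in sex, and no setting separates these.

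Of the main counts and tests, 223 values under alternatives kept their direction and side of the threshold or stayed within 1.5 times, 15 moved, 1 became stronger, 1 weaker and 0 reversed. Requiring a change of at least 2-fold, which by construction removes smaller changes, left 4031 genes for challenge in wild-type, 826 in knockout, 677 for genotype without challenge, 2173 after it, 819 averaged and 2216 for the interaction. Limma-voom with quality weights called 3177 genes for genotype without challenge against 1955, and the cause was not tested. With an estimated correlation, camera called 2 lists for challenge in wild-type, 2 in knockout, 6 for genotype without challenge, 2 after it, 1 averaged and 2 for the interaction, and the cause was not tested. The mixed fry test, which asks for change in either direction, called 31 lists for genotype without challenge and 32 averaged. Counting only 8mer sites, miR-27a after challenge shifted by 0.033 (permutation p = 0.0596), and counting 7mer-A1 sites too, miR-24 after challenge shifted by 0.016 (permutation p = 0.0328), and the cause was not tested.

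Leaving out 1 library at a time gave 9784 to 10127 genes for challenge in wild-type, 3388 to 4935 in knockout, 1393 to 1605 for genotype without challenge, 7152 to 8179 after it, 5397 to 6451 averaged and 5167 to 6423 for the interaction. Lists called were 26 to 27, 21 to 23, 12 to 15, 24 to 25, 20 to 22 and 24 to 26 in the same order. Replicate blocks gave 9714, 3078, 1469, 7255, 5298 and 4995 genes, although the values gave no sign that the numbers mark pairs. Without X and Y the counts were 10295, 4396, 1921, 7916, 6037 and 5751, and without markers of other cells 10433, 4365, 1818, 7967, 6081 and 5755.

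Upper-quartile scaling moved the median gene by -0.11 for challenge in wild-type, where 4634 genes rose and 6184 fell. It turned the share of raised genes from 57.5% to 46.7% for challenge in knockout, from 46.7% to 56.7% for genotype after challenge, from 48.8% to 59.4% averaged and from 47.5% to 55.3% for the interaction. Which scaling is nearer to the cells was not tested, so the balance of directions depends on it.

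The genes of the naming rule, up to 4 members of each list included, were refitted 20557 times over 998 pairs of gene and contrast. In 20083 fits the status, called or not called, stayed the same, in 370 a call was lost, in 103 a call was gained and in 1 the sign turned, and 69 pairs lost their call somewhere. The sign turned for Eif2s3y in the challenge of wild-type (-7.1), which became 4.06 without unchallenged wild-type replicate 4 (adjusted p = 0.311), the library with Y-linked transcripts, and lost its call at -8.86 without challenged wild-type replicate 2 (adjusted p = 0.1).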

Other observations

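The site comparisons and their alternatives were planned, whereas the reading of them as a test of lost repression, the other splits of the libraries, the kept part of the change and the genes seen only in challenged knockout libraries were chosen after the values were seen.

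Several gene groups showed differences in response beyond those already described. Of 48 interferon-stimulated genes, 44 had a negative interaction term (45 adjusted over the list alone, median -1.09, camera adjusted p = 4.09e-22, adjusted p = 0.076 with an estimated correlation), with Rsad2, an antiviral enzyme gene, at -2.25 and Isg20 at -2.08. Of 46 cell-cycle genes, 44 were negative (45 adjusted over the list alone, median -1.11, camera adjusted p = 1.84e-20, adjusted p = 0.0809 with an estimated correlation), with Rrm2 at -1.54. Platelet markers had 12 positive and 1 negative of 14 (the same adjusted over the list alone, camera adjusted p = 8.24e-08, adjusted p = 0.101 with an estimated correlation). With challenge, 12 of them fell in wild-type and 6 rose in knockout, Ppbp going from 125 ± 21 to 35.3 ± 2.5 CPM and from 31.7 ± 3.2 to 62.2 ± 9.3 CPM. The plasmacytoid dendritic-cell receptor gene Siglech fell in both, with changes of -3.81 and -0.74. The IgA gene Igha was 2.93 higher in unchallenged knockout and 1.75 higher in challenged knockout libraries. The plasma cell markers as a list did not follow it, with 1 higher and 6 lower of 11 without challenge (median -0.43) and 4 higher and 5 lower after it (median -0.3). Of the genes with a called interaction, 131 were called in opposite directions in the genotypes.

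The kept part of the wild-type change in CPM differed between some groups of genes. Over all raised genes it was 0.27 (0.23 to 0.31). Several raised lists lay near that value, with ranges that overlap it: glycolysis at 0.25, heat shock genes at 0.27, the interferon-gamma list at 0.3 and cell-cycle genes at 0.31. It was 0.15 for raised TRAF6 to NF-kB genes (0.11 to 0.24 over the 3 challenged knockout libraries), 0.21 for cytokines (0.17 to 0.25), 0.3 for interferon-stimulated genes (0.24 to 0.34) and 0.43 for macrophage markers (0.31 to 0.54). Each of these ranges also overlaps or touches that of all raised genes, so these lists are not set apart from it. Over all lowered genes the kept part was 0.39 (0.38 to 0.43). Among lowered genes it was 0.37 for NK receptors (0.24 to 0.51), 1.53 for erythroid markers (1.27 to 1.83) and -0.16 for platelet markers (-0.22 to -0.08). Only the erythroid and platelet ranges lay apart from that of all lowered genes. The erythroid value reflects the higher level in unchallenged knockout, since on the log2 scale the 10 markers called at 2-fold in wild-type had medians of -2.61 there and -0.68 in knockout, and all 10 changed less in knockout. Each challenged knockout library reached 2 CPM for St6galnac1 (mean 3.61 CPM), Gm13841 (16.9), Gm8210 (16.9), Gm3375 (4.6) and Rpl3-ps1 (310 CPM), with at most 0.5 CPM in any other library. Gm13841, Gm8210 and Rpl3-ps1 are annotated as processed pseudogenes, so the source of their reads is uncertain. Gm13841 and Gm8210 had the same mean and the same highest level elsewhere (0.0467 CPM), so their reads are not separable with certainty.

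Loss of repression by the 3 miRNAs was tested as a hypothesis. In 0 of 9 tests did the shift of genes with 3' UTR sites lie above those of all shuffled seeds, although 8 of 9 lay above matched random lists, so a contribution may exist or not and cannot be told apart from a general property of such UTRs.

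For single comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real counts and the highest other were 10577 and 0 genes for challenge in wild-type, 4511 and 0 in knockout, 1955 and 1 for genotype without challenge and 8124 and 0 after it, with 1 split as large in each, the real one. For the average over treatments, 1 of 100 drawn splits, the real one, reached 6218 genes, and the highest other gave 5876. A chance assignment is excluded at a share of 0.05 only if the libraries are independent, which the labels do not say.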
